A study of Homo sapiens with 20 samples.

How the data were processed

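Antibody-directed tagmentation libraries were analysed from cytotrophoblast-like cells made from stem cell lines. Per the labels, the control line carries an mCherry reporter at GATA3, the knockout line lacks SP6 on that background, and a further line carries HA-tagged SP6. SP6 is a zinc finger transcription factor of the SP/KLF family. H3K4me3 (a mark of promoters), H3K27ac (a mark of active promoters and enhancers), P300 (an acetyltransferase found at enhancers) and H3K27me3 (the Polycomb mark) were each profiled in 2 control and 2 knockout libraries. HA was profiled in 2 libraries of the tagged line, and IgG in 1 control and 1 knockout library, which makes 20 libraries. Per the labels' protocols, permeable cells were incubated with an antibody and then with an adaptor-loaded transposase, and Drosophila DNA was added to the H3K27ac and P300 lysates. Whether that added DNA was used in the peak calls is not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures. Comparisons of groups of libraries thus rest only on the spread between these libraries, which may be technical.

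Per the submitters' processing notes, 12 libraries (H3K4me3, H3K27me3, IgG and HA) were processed with Bowtie2, Picard, MACS2 2.2.7.1 and deepTools, and the 8 H3K27ac and P300 libraries with cutadapt 4.3, Bowtie2 2.2.5, SAMtools 1.13, Picard 2.7, MACS2 2.2.7.1 and HOMER 4.11. The authors deposited 1 broad peak list per library, so peaks were called per sample and replicates could be compared. Each deposited peak has a score, which was not used. Each deposited peak also has a fold enrichment over the local background, a ratio computed by the authors' peak caller, and the −log10 of its p-value and of its q-value, again as the authors deposited them. These values belong to the peak in its own list and were used only to rank or filter peaks.

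The processing notes name GRCh38 for the 12 libraries and hg19 for the other 8. The positions in all 20 lists were those of hg19. Each list named unplaced contigs in the hg19 style, and in the 10 H3K4me3, H3K27me3 and HA lists of the first set peaks lay past the last GRCh38 gene of at least 13 chromosomes, by up to 2.25 Mb to 2.61 Mb. All positions are therefore given in hg19, 1-based, and marks were compared with each other by position. The gene table at hand describes GRCh38.p14, and positions were not converted between builds. Promoters, gene names, gene lists, the MSX2 and SP6 loci and motifs were not analysed here, although tests of them had been designed. Merged regions took the place of promoters, and H3K4me3 separated the sites of promoter type from the rest.

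Peaks on chromosomes 1 to 22 and X were used. For each mark, the peaks of its 4 libraries were merged where they overlapped by at least 1 bp. A region was called lost when both control libraries and neither knockout library held a peak in it, and gained in the reverse case. These counts were set against those of the other 2 ways to split the 4 libraries into pairs, with 1 control and 1 knockout library on each side. Such splits balance the genotypes. A difference of calling floor or enrichment between control and knockout libraries is thus not part of the error they measure. SP6-HA sites were merged regions held by both HA libraries and by no IgG peak. No HA library of cells without the tag was analysed here, so IgG of the other lines is the only background. Chance overlap was measured by placing regions at random on their own chromosome outside stretches of 500 kb or more without any peak, 100 times for SP6-HA sites and 20 times for lost and gained regions. Odds ratios come from Fisher's exact test, two-sided. Regions and sites are not independent replicates, so these p-values describe the lists and not the cell lines. Group values were compared by exact two-sided permutation of the 4 libraries. With 2 libraries against 2, the smallest p that test can give is 0.333, so no such comparison could reach 0.05.

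Peak lists do not give read counts. The weakest peaks of each list were used to recover what its calls rested on, since the commonest pair of fold and −log10 p in a list has 1 solution as a whole number of overlapping fragments over a Poisson background. The solution matched the deposited −log10 p to within 9.76e-06. The weakest peaks held 4 fragments in most libraries, 5 in knockout replicate 1 of H3K27ac and in the knockout IgG library, and 3 in the control IgG library. The background, which rises with the number and length of the fragments, was 0.694 ± 0.0308 in control and 1.02 ± 0.0151 in knockout for H3K27ac (SD, n = 2), 0.66 ± 0.0703 and 0.773 ± 0.0471 for P300, 0.583 ± 0.0101 and 0.569 ± 0.00175 for H3K4me3, and 0.715 ± 0.00215 and 0.584 ± 0.0225 for H3K27me3. As a result, the lowest fold that could enter a list ran from 2.49 to 2.99 for H3K27ac and from 2.91 to 3.19 for H3K27me3. A weak peak could thus be listed in one library and fall under the floor of another with no difference in the cells.

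The design, the groups and the tests of covered length and of SP6-HA sites were fixed before the data were examined. So were those of lost and gained H3K27ac and P300 regions. For H3K4me3 and H3K27me3 the design had promoters as the unit, and merged regions took their place once the build had been seen. Loss of H3K27ac and P300 at regions with an SP6-HA site was not in the design. The alternatives fixed in advance were a −log10 q of at least 5, lists of equal length, libraries left out, a replicate block, IgG peaks removed and a stricter overlap. Lists of equal length held the strongest peaks by −log10 p, as many as the shortest list of the mark holds. The same fold minimum of 4 or 5 in every library, the division of SP6-HA sites by H3K4me3, the use of one build for all marks, the strata of region width, and peaks of 10 kb or more were added after the data had been seen. By a rule fixed in advance, the text names regions from the 5 lost and the 5 gained regions of each mark with the highest mean rank by −log10 p within their own lists, and from the 5 such SP6-HA sites.

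The step that calls lost and gained regions was tested on simulated data. The simulation had 10000 regions per mark, 200 changed in each direction and peaks missed at random at a set rate. It recovered 86.5% (P300 gained) to 93.5% (H3K27ac gained) of the changed regions, with 20 to 26 false calls. The set rate largely fixed these values in advance, so they check the code only. Real libraries of a genotype shared 35.98% to 67.0% of covered bases, so the error of the real calls is not measured by them. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.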

Results

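To follow what SP6 does to chromatin as human stem cells turn into trophoblast, 3 histone marks and the acetyltransferase P300 were mapped in cytotrophoblast-like cells with and without SP6, and SP6 itself was mapped through an HA tag. Each mark had 2 control and 2 SP6 knockout libraries, HA had 2 libraries, and IgG had 1 library in control and 1 in knockout. The lists held 1587700 peaks in total. IgG gave 1945 peaks in control and 3010 in knockout, covering 1.00 Mb and 1.93 Mb, against 62.2 Mb or more in any library of a histone mark or P300. Because reads are not in the lists, the depth behind a peak is known only through the background its caller used. The mark libraries of a genotype shared from 35.98% of their covered bases (H3K27me3 control) to 67.0% (H3K4me3 control), and the HA replicates shared 30.4%.

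Cells without SP6 had more H3K27ac peaks but far fewer strong ones. The number of peaks rose from 88828.5 ± 1083 in control to 149206 ± 47786 in knockout (SD, n = 2), and the length they covered from 159 ± 8.80 Mb to 268 ± 78.8 Mb, a log2 ratio of 0.76. Peaks with at least 5-fold enrichment went the other way, from 12133 ± 689 to 3671.5 ± 1397, and the 99th percentile of fold from 10.99 ± 0.270 to 5.57 ± 0.438. Control and knockout libraries did not overlap in any of these values. The exact permutation p was 0.333 for each, the smallest that 2 against 2 allows. The rise in covered length leaned on knockout replicate 2, without which the log2 ratio was 0.42, and the direction depended on the threshold, with a log2 ratio of -0.66 for peaks with a −log10 q of at least 5.

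By position, 9298 H3K27ac regions were lost and 34057 gained in the deposited lists, where the other 2 splits of the libraries gave 5512 and 5316 changed regions. With lists of equal length the counts were 15626 lost and 17734 gained, and with at least 5-fold enrichment in every library 6741 lost and 353 gained. The balance of loss and gain was thus set by the threshold, whereas the number of changed regions was above both other splits each time. Those splits balance the genotypes, so a difference of floor or enrichment between control and knockout libraries could also give this excess. Among the strongest lost regions were chr15:96385595-96392781 and chr15:96863221-96900445, the latter 37.2 kb wide, each with an SP6-HA site. In the former the H3K4me3 and P300 peaks of both control libraries were also missing from both knockout libraries. It had a fold of 10.2 and 9.63 in the control replicates. Also among the 5 strongest lost regions, chr4:156522504-156526487 and chr4:148228899-148238836 held no SP6-HA site. Of these, chr4:156522504-156526487 overlapped an IgG peak. The strongest gained regions included chr5:12622527-12628201, with a fold of 7.89 and 8.63 in knockout and P300 gained in both libraries and 3 regions of chromosome 4, at chr4:180084541-180097907, chr4:187161267-187192303 and chr4:189364806-189366055. None of the 5 strongest gained regions held an SP6-HA site, but few such sites lie outside control H3K27ac peaks.

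**Figure D1:**
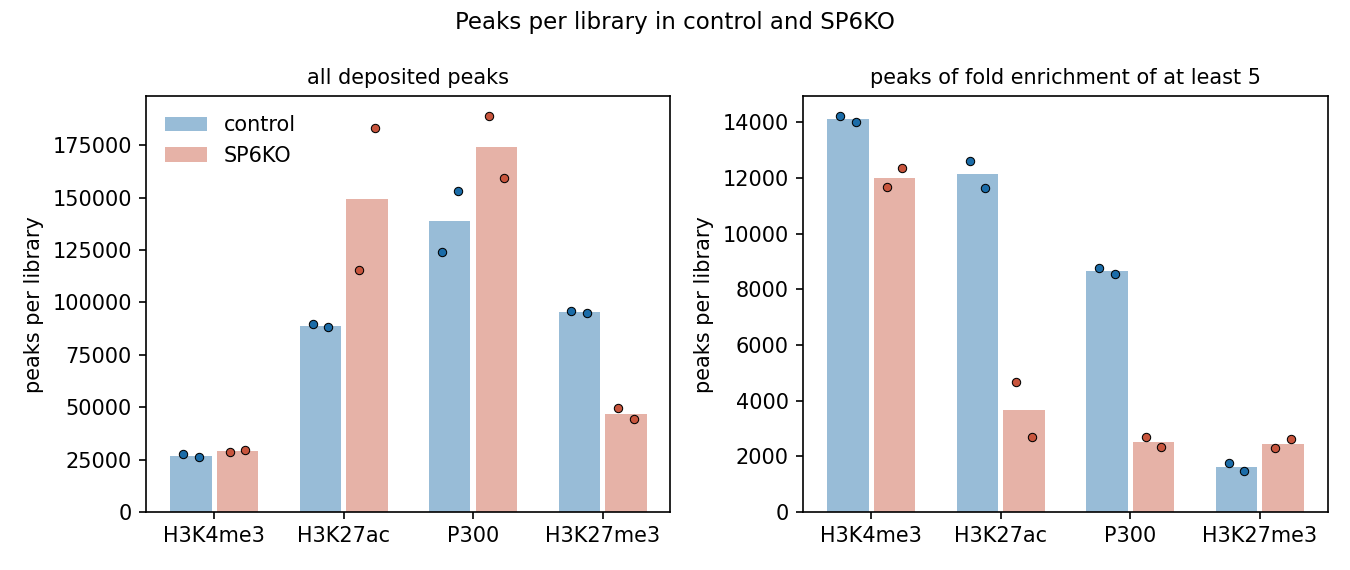
Number of peaks per library, for each mark in control and SP6 knockout. Points are the 2 libraries and bars their mean. For H3K4me3, H3K27ac and P300 the knockout libraries lie above control when all deposited peaks are counted. They lie below control when only peaks of at least 5-fold enrichment are counted. For H3K27me3 the order is the reverse.

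P300, the enzyme that writes H3K27ac, changed in the same way. Its peaks numbered 138685 ± 20677 in control and 174066 ± 20768 in knockout (SD, n = 2), and the length covered went from 148 ± 28.1 Mb to 214 ± 23.1 Mb (log2 ratio 0.53). Peaks of at least 5-fold enrichment fell to 2527.5 ± 250 from 8648 ± 148, a log2 ratio of -1.77. The exact permutation p was again 0.333. The log2 ratio of covered length was 0.35 without control replicate 1, and -1.83 for peaks with a −log10 q of at least 5.

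In the deposited lists 13760 P300 regions were lost and 30589 gained, against 10510 and 9059 changed regions in the other splits. At 5-fold or more, 3952 were lost and 179 gained. The strongest lost region, chr15:96388609-96390890, lay inside the lost H3K27ac region of chromosome 15 and held an SP6-HA site. So did the lost regions chr5:32785142-32786820 and chr4:96330464-96333072, where H3K27ac was also lost. The lost region chr4:124939929-124940479, also among the 5 strongest, held no site. All 5 of the strongest gained P300 regions, among them chr3:84885402-84886710 and chr5:93651458-93653389, gained H3K27ac as well and had no SP6-HA site. Few such sites lie outside control P300 peaks.

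H3K27ac and P300 peaks were often lost or gained at the same regions. Peak strength was not held fixed in these tests, so regions weak in both marks could fall under both floors together. Where both control libraries held both marks, 52.4% of the regions that lost H3K27ac also lost P300, against 5.26% of those that did not lose it (odds ratio 19.9, Fisher's exact test). For gain, among regions with no control peak of either, the shares were 45.5% and 7.97% (odds ratio 9.65). The odds ratios were smaller for stronger peaks, at 9.54 for loss and 7.16 for gain with at least 4-fold enrichment, and 3.25 and 3.67 with a −log10 q of at least 5. Randomly placed regions gave 20.1-fold less overlap for loss and 8.73-fold less for gain, and at 5-fold or more 18.1-fold and 87.3-fold less, the last for 48 regions. Of the lost H3K27ac regions 0.796% lay over a gained P300 region, 0.256 times the random value, which was 0.526 times at 4-fold and 1.49 times (5 regions) at 5-fold. Each region of the test for gain holds some knockout peak by construction, which lowers its odds ratio. Both p-values were too small to be represented as a number.

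H3K4me3 covered more of the genome in knockout. A control and a knockout library shared 56.3% to 56.8% of the covered bases, against 67.0% for the control and 61.7% for the knockout libraries among themselves. Control libraries had 26875 ± 755 peaks and knockout libraries 29187 ± 547 (SD, n = 2), and covered length rose from 62.9 ± 1.02 Mb to 76.5 ± 1.64 Mb (log2 ratio 0.28, exact permutation p = 0.333). The peaks became wider at the upper end, with 286.5 ± 0.707 of 10 kb or more in control and 718.5 ± 40.3 in knockout. Peaks of at least 5-fold enrichment were fewer, at 12006.5 ± 483 in knockout against 14117 ± 148 in control. The 99th percentile of fold was 20.4 ± 0.627 in control and 14.6 ± 0.836 in knockout. Of the 44609 merged regions, 16767 held a peak in all 4 libraries, 1616 were lost and 1394 gained, against 904 and 886 changed regions in the other splits. None of the strongest decile of control regions (0 of 2000) was lost and none of the strongest decile of knockout regions (0 of 1935) was gained. With 5-fold enrichment required in every library 1013 regions were lost and 111 gained.

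Among the strongest lost H3K4me3 regions were chr18:52271478-52276281 and chr3:112012334-112013350, and both kept H3K27ac and P300 in all libraries. The region chr10:20658671-20661301 was lost too, but it overlapped an IgG peak. Of the 5 strongest gained regions, 3 were on chromosome 19, at chr19:22714512-22715985, chr19:37794530-37796398 and chr19:38041477-38042994, and all 3 gained P300 in both knockout libraries with no P300 peak in control. Lost H3K4me3 regions overlapped lost H3K27ac regions 13.5 times as often as randomly placed regions, in 15.0% of cases, and kept ones 4.44 times as often, in 40.8%. At 5-fold or more these were 7.35 times (18.4%) and 2.45 times (3.16%).

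H3K27me3 peaks were fewer in the deposited knockout lists, while strong and wide peaks were more numerous. The knockout libraries held 46866.5 ± 3654 peaks against 95393 ± 472 in control (SD, n = 2), and the length covered was 96.7 ± 0.127 Mb against 150 ± 1.09 Mb, a log2 ratio of -0.64 (exact permutation p = 0.333). Strong peaks went up, from 1629 ± 204 to 2443.5 ± 228 at 5-fold or more. Peaks of 50 kb or more rose from 7.5 ± 2.12 to 38.5 ± 3.54. The length of peaks of at least 5-fold enrichment was 7.36 Mb and 6.17 Mb in the control libraries and 25.2 Mb and 28.9 Mb in the knockout libraries.

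The deposited lists gave 16605 H3K27me3 regions lost and 1467 gained, where other splits gave 4258 and 4233. With lists of equal length the counts were 3970 and 3478, and with a −log10 q of at least 5 the covered length had a log2 ratio of 2.78, so the direction turned with the threshold. At 5-fold or more 226 regions were lost and 978 gained, with a median width of 2062.5 bp for lost and 10525 bp for gained regions. An SP6-HA site was held by 40.3% of these lost regions, 37.2% of the gained and 35.1% of the kept ones. Because the widths differ, these shares are not alike relative to random placement, at 12.8 times random for lost and 4.06 times for gained regions. The regions with the highest ranks included chr8:66470097-66473346 and chr5:95170410-95172542 among those lost, and chr7:153583064-153588372 and chr12:31269779-31273163 among those gained. In the last of these H3K27ac was held by both control libraries and by neither knockout library. For H3K4me3 and H3K27me3 the control and knockout libraries have separate runs of library numbers, so a batch and the genotype could not be separated.

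**Figure D2:**
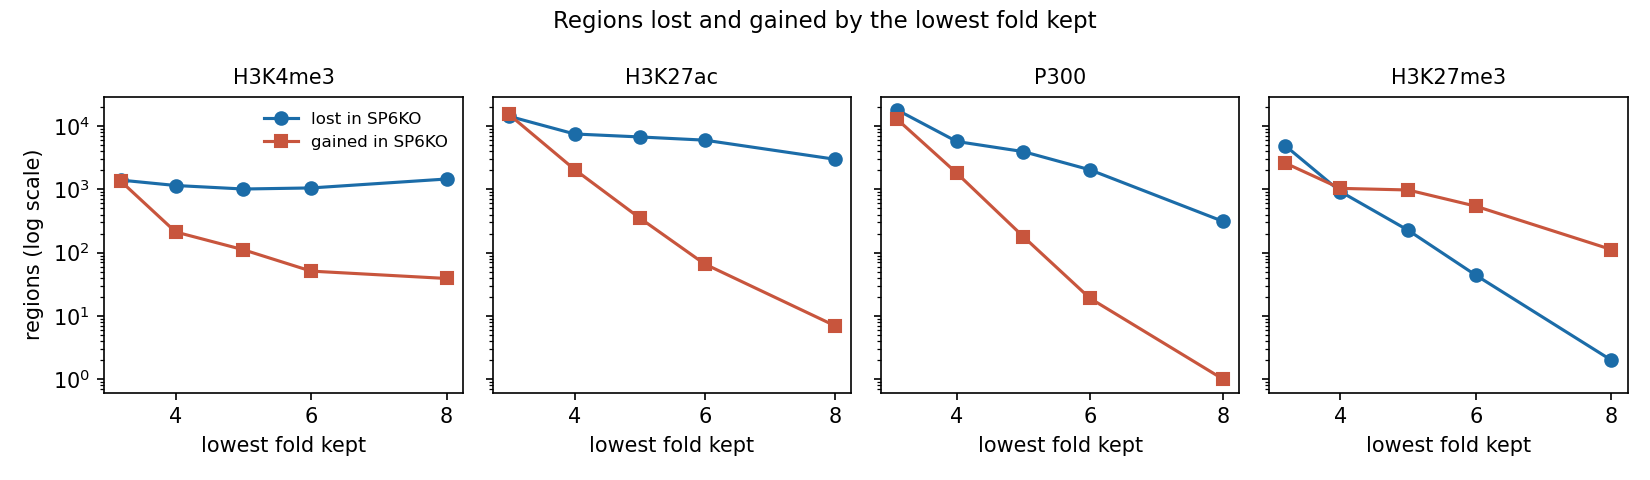
Regions lost and gained in SP6 knockout (log axis) against the lowest fold enrichment kept in every library of the mark, from the highest of the libraries' own floors to 8. Gains of H3K27ac and P300 drop faster than losses as the minimum rises. Gains of H3K4me3 drop to 39 while losses go from 1401 to 1458. For H3K27me3 losses drop faster, to 2 lost and 112 gained at 8.

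Regions with peaks of both H3K4me3 and H3K27me3, called bivalent below, were fewer in knockout in the deposited lists. The term stands for overlap of peaks only, since promoters and developmental genes were not analysed. Most of these overlaps needed weaker peaks, with 227 regions left in control and 540 in knockout at a −log10 q of at least 5. In control 10975 of 19996 H3K4me3 regions (54.9%) also held H3K27me3 in both libraries, and in knockout 9646 of 19346 (49.9%). Both lines held 7683 of them, 844 lost H3K27me3 and 450 lost H3K4me3. The order turned with a common minimum of 4-fold (2697 in control, 2942 in knockout) and with lists of equal length (8321 and 9183). An SP6-HA site was held by 45.4% of the bivalent and 41.9% of the other H3K4me3 regions in control, an order that also turned at 4-fold (42.4% and 54.3%) and with lists of equal length (43.3% and 44.7%).

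SP6-HA sites lay mostly in control peaks of H3K27ac and P300, and more often than random in H3K27me3 peaks too. With 2 short IgG lists as the only background, HA signal unrelated to SP6 cannot be told apart from binding. Both HA libraries shared 19260 regions, of which 2453 overlapped an IgG peak, and the remaining 16807 were taken as SP6-HA sites (median width 1464 bp, 31.2 Mb in all). In control cells 59.0% ± 0.526 of the sites lay in H3K4me3 peaks (SD, n = 2), 90.7% ± 0.0379 in H3K27ac peaks, 94.8% ± 1.67 in P300 peaks and 53.5% ± 1.40 in H3K27me3 peaks. Random placement gave 5.38%, 13.8%, 14.4% and 13.1% against the peaks of control replicate 1. H3K27ac and P300 were both present in both control libraries at 14149 sites (84.2%). An H3K4me3 peak was present in all 4 libraries at 8979 sites (53.4%) and in none at 4781 (28.4%). Of the 5 strongest sites, chr10:134349891-134351722 (fold 11.1 and 16.6), chr21:46492287-46496371 (12.1 and 11.6) and chr13:111566427-111568320 (11.4 and 12.1) held all 4 marks in all libraries. The other two, chr1:143913200-143913635 and chr1:206137965-206138410, held H3K27ac in both control libraries and 1 knockout library, and the latter had no H3K27me3. Only 49.7% of the peaks of HA replicate 1 overlapped a peak of replicate 2, and 480 sites were left with a −log10 q of at least 5, 95.4% of them in H3K4me3 peaks of both control libraries.

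Without SP6, fewer of these sites lay in H3K27ac and P300 peaks. The share in H3K27ac peaks was 80.8% ± 8.07 and that in P300 peaks 83.8% ± 2.31 in knockout (SD, n = 2). The differences of -9.90 and -11.0 percentage points became -18.7 and -15.1 with lists of equal length and -36.4 and -25.0 with peaks of at least 5-fold enrichment. At 5-fold the shares went from 49.8% to 13.4% (H3K27ac) and from 31.6% to 6.59% (P300). All peaks of that strength fell to 0.303 and 0.292 times control, so this drop cannot be read as particular to SP6-HA sites. H3K4me3 was held at 63.9% ± 0.492 of the sites in knockout. The exact permutation p was 0.333 for each mark. The H3K27ac difference was -4.19 points without knockout replicate 1 and -15.6 without replicate 2. For H3K27me3 it was -7.80 points in the deposited lists and 4.56 with lists of equal length.

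With lists of equal length the decline was larger at sites without H3K4me3, the class that holds enhancers. There the share in H3K27ac peaks went from 75.2% ± 0.385 to 39.1% ± 4.38 and that in P300 peaks from 82.1% ± 1.33 to 43.6% ± 0.532 (SD, n = 2). At sites with H3K4me3 in all 4 libraries the shares went from 98.4% ± 0.0630 to 90.1% ± 1.24 and from 99.8% ± 0.0866 to 98.5% ± 0.173. These classes use the knockout libraries, so loss was also tested with classes from the control libraries alone, added after the data had been seen. Of the sites with H3K27ac in both control libraries, 18.6% of those with no control H3K4me3 peak and 2.05% of those with one in both lost it in the deposited lists (odds ratio 10.9, Fisher's exact p = 2.79e-245, and 4.71 within strata of control rank). At 5-fold or more these were 85.9% and 62.5% (odds ratio 3.66, Fisher's exact p = 9.02e-51, and 2.11 within the strata). With that minimum the share in H3K27ac peaks went from 73.1% ± 1.48 to 21.4% ± 5.24 at sites with H3K4me3 in all 4 libraries and from 16.1% ± 0.458 to 2.11% ± 0.385 at H3K4me3-free sites. In percentage points that drop was larger at the former, and relative to the control share it was larger at the latter.

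**Figure D3:**
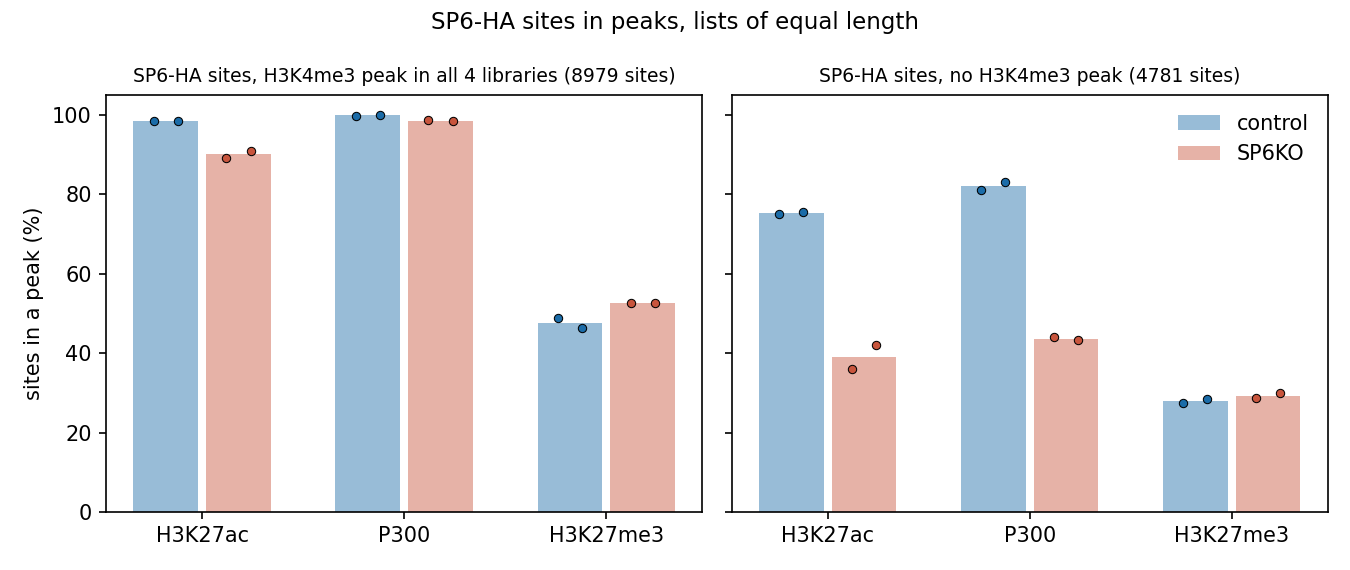
Share of SP6-HA sites (percent) that lie in H3K27ac, P300 and H3K27me3 peaks, for sites with an H3K4me3 peak in all 4 libraries and sites with none, with lists of equal length within a mark. Points are libraries and bars their mean. At H3K4me3-free sites the P300 bar stands at 82.1% in control and 43.6% in knockout.

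In the deposited lists, regions with an SP6-HA site were lost less often than those without. Of the H3K27ac regions of both control libraries, 6.55% of those with an SP6-HA site and 24.9% of those without were lost (odds ratio 0.211, Fisher's exact test). The values for P300 were 7.66% and 23.5% (0.270), for H3K27me3 13.0% and 43.3% (0.196) and for H3K4me3 1.14% and 13.5% (0.0740, Fisher's exact p = 3.26e-272). The odds ratio was 0.423 within strata of control rank and 0.606 within strata of width for H3K27ac, 0.220 and 0.248 for H3K4me3, and 0.310 and 0.193 for H3K27me3. Width is that of the region merged over all 4 libraries, so it depends on whether knockout peaks are present. Strata of width therefore cannot show what width contributes. At 4-fold the H3K27me3 odds ratio was 0.747, and 0.864 within strata of width, and at 5-fold 1.26 and 1.70. At 5-fold or more that for H3K27ac was 0.734, and 0.916 and 0.984 within the strata. For P300 the odds ratio within strata of region width was 1.17 in the deposited lists, 1.04 with lists of equal length and 0.857 at 4-fold, so its direction there depended on the setting. Within strata of control rank it was 0.707, 0.706 and 0.677 in these settings, and 1.16 at 5-fold or more. The direction turned for P300 at 5-fold or more (67.1% against 58.7%, odds ratio 1.44, Fisher's exact p = 6.68e-11), and for H3K27me3 at a −log10 q of at least 5 (odds ratio 1.36, Fisher's exact p = 0.201).

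Among regions without H3K4me3 the gap between those with and without an SP6-HA site depended on the setting. In the deposited lists 24.3% of the H3K27ac regions with an SP6-HA site and 33.0% of those without were lost (odds ratio 0.652, Fisher's exact p = 2.80e-17), and at 4-fold or more 87.8% and 85.4% (1.23, Fisher's exact p = 0.134). With lists of equal length 47.3% of the H3K27ac regions with an SP6-HA site and 52.0% of those without were lost (odds ratio 0.827, Fisher's exact p = 2.67e-05), and 40.1% and 42.6% of P300 regions (0.902, p = 0.00888, Fisher's exact test). Within strata of width these odds ratios were 1.74 and 2.15, and within strata of control rank 0.898 and 1.0995. The widths include knockout peaks, which only regions that were not lost can have. Strata of width thus depend on the outcome and cannot show whether regions with a site were lost more often than others of like width. Gained H3K27ac regions held an SP6-HA site in 0.393% of cases and gained P300 regions in 0.163%, which is 0.193 and 0.0888 times the share of randomly placed regions. A gained region has no control peak by definition, and control peaks of these marks held 90.7% and 94.8% of the sites. Low shares were thus built in, and random placement, which may fall in control peaks, cannot test whether gained regions avoid SP6-HA sites. The shares were 0.338% and 0.160% with lists of equal length. They were 3.79% and 4.04% (0.956 and 1.36 times random) at 4-fold or more, and 7.37% and 6.15% (1.27 and 2.39 times) at 5-fold or more. At 4-fold control peaks held only 65.5% and 63.0% of the sites, which leaves more of them free for gained regions.

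In SP6 knockout the share of H3K27ac length was lower on autosomes rich in H3K4me3 and higher on autosomes poor in it, and the share of H3K27me3 changed the opposite way. The length itself rose on 21 of 22 autosomes for H3K27ac (log2 ratio 1.52 on chromosome 4 and -0.11 on chromosome 19) and fell on all 22 for H3K27me3 (log2 ratio -1.14 and -0.13), so the shares show unequal rises and falls. As shares of covered length, the log2 change of H3K27ac ran from -0.86 on chromosome 19 to 0.78 on chromosome 4, that of P300 from -0.36 on chromosome 22 to 0.44 on chromosome 4, and that of H3K27me3 from -0.51 on chromosome 4 to 0.50 on chromosome 19. The share of H3K4me3 changed opposite to that of H3K27ac (r -0.888) and with that of H3K27me3 (r 0.836). The shift followed the density of H3K4me3 regions held by all 4 libraries, which ranged from 3.54 to 23.7 per Mb. Pearson's r was -0.781 for H3K27ac (permutation p = 1e-05, adjusted 1.5e-05, Spearman's rho -0.862 with p = 1e-05), -0.594 for P300 (permutation p = 0.00083, adjusted 0.00083, rho -0.723 with p = 0.00025) and 0.793 for H3K27me3 (permutation p = 1e-05, adjusted 1.5e-05, rho 0.876 with p = 1e-05), over 22 autosomes and adjusted by Benjamini-Hochberg over the 3 marks. The smallest p that these permutations can give is 1e-05. Without the 2 autosomes farthest from the median density r was -0.856, -0.694 and 0.762. Split by replicate number, r was -0.780 and -0.781 for H3K27ac, -0.633 and -0.551 for P300, and 0.798 and 0.783 for H3K27me3. This comparison was added after the data had been seen, and chromosomes of one cell line are not independent replicates.

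**Figure D4:**
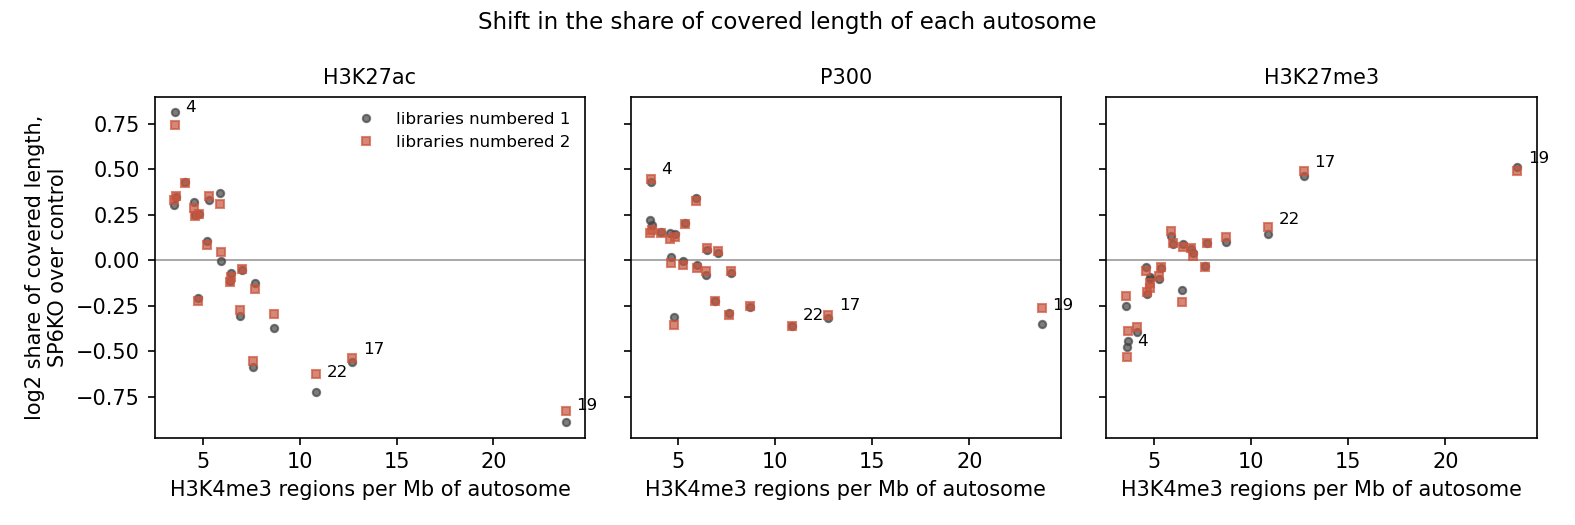
Log2 share of covered length, SP6 knockout over control, for each of the 22 autosomes against the number of H3K4me3 regions per Mb. Each autosome has a point for the libraries numbered 1 and one for those numbered 2, and chromosomes 4, 17, 19 and 22 are named. H3K27ac and P300 slope down (r -0.781 and -0.594) and H3K27me3 slopes up (r 0.793).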

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

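Of the tests in this part, those of different list lengths were set before their result was seen, and the rest were chosen after it. Outside the chromosomes analysed, every group of HA, mark or P300 libraries had more peaks on unplaced contigs than either IgG library, which had 9 and 14. The mean number was 48 for H3K27ac in knockout and 42.5 in control, 72 and 57 for P300, 37.5 and 48.5 for H3K27me3, 27.5 and 32.5 for H3K4me3, and 48.5 for SP6-HA. IgG lists are shorter, with 1945 and 3010 peaks on the chromosomes analysed. Relative to list length, each IgG library had more contig peaks than any other library, and no explanation was tested.

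Strong H3K27ac and P300 peaks were fewer in knockout. So were strong H3K4me3 peaks, from another set of libraries, with 12006.5 ± 483 against 14117 ± 148 in control at 5-fold or more. For H3K27ac and P300 lower sequencing depth is argued against. The background the caller used was at least 1.04 times as high in every knockout library as in any control library of the same mark. Of the strongest decile of knockout H3K27ac regions, 7.97% had no control peak with lists of equal length, against at most 2.498% that one library lacked from its replicate, but the deposited lists gave 10.3% against 6.22%. For P300 the values were 5.26% against 4.09% and 5.63% against 5.15%. For both, a weakening of all peaks alike, from a less enriched library, cannot be told apart from a change of place, and the loss of SP6 remains open as well.

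More H3K27me3 regions were lost than gained in the deposited lists. The deposited lists gave 16605 and 1467, and with the highest floor of the libraries as the minimum for all, 4879 were lost and 2599 gained, or 1.88 lost per region gained, and 0.890 at 4-fold or more. A lower calling floor in the control libraries may thus account for part of the excess, and for the rest it cannot be told apart from a change in the cells. The stronger and wider knockout domains lie above the floor of every library. An effect of SP6 and a difference between the separate runs of libraries both stay open for these domains.

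The shares of chromosomes in the covered length also changed. That of H3K27ac had a log2 ratio of -0.86 on chromosome 19, rich in H3K4me3 regions, and 0.78 on chromosome 4, poor in them, and that of H3K27me3 0.50 and -0.51. A changed number of chromosomes in the knockout line would move the shares of all marks the same way, but the shifts of H3K27ac and H3K27me3 had a Pearson r of -0.77 over 22 autosomes. Different list lengths are argued against too, since r with the density of H3K4me3 regions was -0.761 for H3K27ac and 0.695 for H3K27me3 with lists of equal length. What stays open is the loss of SP6, and weak peaks of less enriched knockout H3K27ac and P300 libraries. The shift was computed for deposited lists and lists of equal length, and is not given with a fold minimum. A difference between sets of libraries stays open too, since H3K4me3 changed with H3K27me3 (r 0.836) of its own set and opposite to H3K27ac (r -0.888) of the other. So does a background of different base composition, which needs reads to test.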

How the results depend on the processing

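The alternatives of a −log10 q of at least 5 and of lists of equal length were fixed in advance for covered length, regions and SP6-HA sites. For H3K4me3 and H3K27me3 the design had promoters in place of regions. The 4-fold minimum, the strata of width, and these settings for peaks of 10 kb or more, bivalent regions, odds ratios of loss and shares of SP6-HA sites were mostly chosen after seeing the data. Promoter windows of 2.5 kb, a promoter overlap of 500 bp, the promoter share of SP6-HA, the motif background and the gene lists were not run, for want of an hg19 annotation. The cause of each change below was not tested, except that stricter settings keep fewer peaks by construction.

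With a −log10 q of at least 5, log2 ratios of covered length were 0.18 (H3K4me3), -0.66 (H3K27ac), -1.83 (P300) and 2.78 (H3K27me3), and of peaks of 10 kb or more -0.13, -1.44 and 3.45 for the last 3. Lost and gained regions were 1012 and 97 (H3K4me3), 3402 and 102 (P300) and 123 and 904 (H3K27me3), and 491 were gained for H3K27ac. SP6-HA sites numbered 480, with 95.4% in H3K4me3 peaks of both control libraries. With all 16807 sites kept and only the mark peaks filtered, the share in peaks changed by -0.890 (H3K4me3), -34.1 (H3K27ac), -21.8 (P300) and 4.31 (H3K27me3) percentage points. The odds ratio of loss at SP6-HA regions was 1.59 for P300 and 1.36 for H3K27me3, and bivalent regions numbered 227 in control and 540 in knockout.

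With lists of equal length, 15626 H3K27ac regions were lost and 17734 gained, 20018 P300 regions were gained, and 3970 H3K27me3 regions were lost and 3478 gained. The H3K27me3 log2 ratio was -0.068. Shares of SP6-HA sites changed by 3.63, -18.7, -15.1 and 4.56 points for H3K4me3, H3K27ac, P300 and H3K27me3. With at least 4-fold enrichment, log2 ratios of covered length were 0.20, 0.029, -0.11 and 0.53 in the same order, and 0.78 for H3K27me3 peaks of 10 kb or more. Gained regions numbered 212 (H3K4me3), 2060 (H3K27ac) and 1805 (P300), lost regions 5713 (P300) and 923 (H3K27me3), and bivalent regions 2697 and 2942. Shares of SP6-HA sites changed by 0.598, -30.0, -27.4 and 1.66 points.

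With 50% of a region required as covered, 2160 H3K4me3 regions were gained. Without peaks over IgG peaks the H3K27me3 log2 ratio was -0.70, and with IgG peaks not removed 60.4% of SP6-HA sites lay in H3K4me3 peaks of both control libraries. A reciprocal overlap left 8113 sites. In strata of region width the odds ratio for P300 loss was 1.17.

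Leaving out 1 library loosens the rule for lost or gained by construction. Lost regions then ranged from 2307 to 5483 (H3K4me3), 10455 to 25149 (H3K27ac), 18162 to 56865 (P300) and 21254 to 56818 (H3K27me3), and gained regions from 1931 to 8669, 38963 to 117030, 36386 to 96442 and 2887 to 13736. Without HA replicate 1 or 2 there were 41087 or 38332 sites, with 30.1% or 32.5% in H3K4me3 peaks of both control libraries. The joint gain of H3K27ac and P300 has no value without a knockout library, since each region tested then holds a gain.

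The replicate numbers did not pair the libraries: same-numbered libraries correlated by -0.0146 (H3K4me3), -0.00285 (H3K27ac), -0.0541 (P300) and 0.00228 (H3K27me3) in 100 kb bins. With a replicate block the log2 ratios of covered length were 0.28, 0.73, 0.54 and -0.64, and no direction changed. In all, 163 values under an alternative were classed as the same, 66 as moved and 14 as reversed, where the same means counts within 1.5 times, other values within the spread, and odds ratios by direction and threshold alone. Such odds ratios moved in size, that of joint H3K27ac and P300 loss from 19.9 to 3.25 and that of H3K27ac loss at SP6-HA regions from 0.211 to 0.741 with a −log10 q of at least 5. Depth limits the weak peaks, which rest on 3 to 5 fragments.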

Other observations

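The counts in this part were chosen after the data had been seen, and no cause was tested. H3K27ac peaks of 50 kb or more numbered 13 ± 2.83 in control and 75 ± 36.8 in knockout (SD, n = 2), and the longest were 327 kb and 334 kb in the knockout libraries against 71.5 kb and 108 kb in control. H3K27me3 peaks of that size also rose, as given above, while H3K4me3 had 2 in knockout replicate 1 and 0 in the other libraries. Lost H3K27ac regions overlapped gained H3K27me3 regions in 2.64% of cases with at least 4-fold enrichment throughout, 5.01 times the random value, and lost H3K27me3 regions in 1.82%, 7.43 times the random value. At 5-fold or more these were 1.498% (1.64 times) and 0.653% (7.04 times).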
